A study of Mus musculus with 14 samples.

How the data were processed

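RNA-seq was run by the authors on epithelial cells from the stomachs of mouse embryos at stage E14.5. The series held 14 libraries in 4 groups, assigned from the submitters' source names and genotypes. Per the labels' protocols, RNA was extracted with a NucleoSpin kit and libraries were made with a directional NEBNext Ultra II kit. The authors deposited 1 table of FPKM values, fragments scaled to transcript length and to the mapped total, with 1 column per library. The aligner, the program that made the FPKM values and the annotation are not given in the sources used here. The submitters' processing notes name the genome build mm9, and no coordinates are printed. How fragments were assigned between paralogs, between overlapping genes or by strand is not given in the sources used here, so genes such as the keratins and Pga5, which have close copies, carry that uncertainty.

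The table had 22906 entries, of which 108 were exact duplicates of another entry and were dropped, leaving 22798 genes. Genes with an FPKM of at least 1 in at least 3 of the 14 libraries were kept, which left 12694. Values were analysed as log2(FPKM + 1) with no further scaling, and fold changes are on that scale, which understates the change of genes with low values. The labels do not say whether the samples of a group came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical. No pair of libraries had more than 90% identical values.

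Absolute depth was unknown because FPKM holds no counts. The relative depth of a pair of libraries was taken from the commonest ratio among genes with FPKM under 0.1 in both, since such values are small multiples of what a fragment is worth. In 90 of 91 library pairs this ratio lay within 0.05 log2 of a common solution, and it was shared by at least 12.7% of these genes. Between the deepest library and the shallowest, at 48.4% of it, precision for weakly expressed genes differs accordingly.

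The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options, using statmod 1.5.0), with 1 mean per group over all 14 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Knockout libraries were compared with hindstomach controls, libraries labelled knock-in with forestomach controls, and hindstomach controls with forestomach controls. The fits, thresholds, filters, gene lists and the rule for named genes were fixed before the data were examined. Single values were compared with two-sided exact permutation tests. Overlaps of calls were tested with a one-sided hypergeometric test, and for comparisons that share controls a simulation of 50 unchanged groups was run.

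In total 28 gene lists were written by hand, for gastric and squamous epithelium, cell junctions, signalling pathways, the cell cycle, sterol synthesis and other cell types. Of these 26 had at least 3 measured genes. The lung and airway list had 2 measured genes and the mitochondrial list 0, and neither was tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, then again with an estimated correlation and with fry. No camera call held with the estimated correlation.

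The genes named are Gata4, Gata5 and Gata6, then for each comparison the 8 genes in each direction with the largest fold change among called genes whose groups did not overlap. Predicted gene models, ribosomal pseudogenes and genes of the sex chromosomes used to tell sex were left out. Groups did not overlap for 42.6% of genes in the knockout comparison, where chance gives 3.57%, for 20.0% in the knock-in comparison and for 41.4% between control regions, where chance gives 10% each. Up to 3 called members of each list with the smallest adjusted p, or else the 2 members with the highest FPKM, were added, and the 8 genes in each direction called in opposite directions in the mutant groups. Gapdh, Epcam, Pgc, Cldn10, Krt20, Cobl, Cdh17, Cdon, Fermt1, Pax9, Col3a1, Xist, Eif2s3y and Hspb1 were named outside this rule, after their values were seen.

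Transcript GC content was taken from an annotation of the GRCm38 assembly, which is not the authors' build. Of the genes kept 12146 matched by symbol and 463 by synonym, 99.33% together. The slope of each library's centred log2(FPKM + 1) on GC entered an added limma fit as a covariate. This fit and other corrections for GC content, transcript length and the first residual component were chosen after the data were examined. The alternatives fixed earlier were another pseudocount, other FPKM filters, rescaling to a common sum, quantile normalization, a fit of the compared groups alone, eBayes without trend, array weights, a fold change threshold, a replicate block and leaving out each replicate.

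The fit was tested on simulated data with 200 genes changed among 12694. A log2 change of 2 was recovered for 82.0% of them in the knockout, 80.0% in the knock-in and 81.0% in the regional comparison, and a change of 1 for 33.5%, 23.5% and 25.5%. In a separate knockout simulation with a GC-linked library bias, 88.0% were recovered without the covariate and 100% with it, with 16 and 9 false calls. Its noise was the same for every gene, so these shares cannot be set beside those above. Its bias was built in proportion to the library slopes, the form that the covariate assumes, so it does not test the covariate on other kinds of bias.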

Results

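Epithelial cells were isolated from the stomachs of mouse embryos at stage E14.5, and their RNA was sequenced in 14 libraries. The mouse stomach has a forestomach, lined by stratified squamous epithelium, and a hindstomach, lined by columnar glandular epithelium. The hindstomach libraries were 3 controls (replicates 2, 3 and 4) and 5 libraries labelled as a knockout of Gata4, which encodes a zinc-finger transcription factor of the foregut endoderm. The forestomach libraries were 3 controls (replicates 2, 3 and 5) and 3 libraries labelled as a Gata4 knock-in (replicates 1, 2 and 4). The labels imply 3 comparisons: the hindstomach without Gata4, the forestomach with added Gata4, and the control hindstomach against the control forestomach. The controls of the hindstomach and of the forestomach came from different crosses, so region and cross could not be separated.

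Gene levels were deposited as FPKM, so the absolute depth of the libraries was unknown. Relative depth was read from the steps between low FPKM values, with hindstomach control 3, the deepest library, set to 100%. The hindstomach controls 2 and 4 then stood at 73.0% and 61.8%, and the libraries labelled knockout 1 to 5 at 85.8%, 84.7%, 48.4%, 74.9% and 84.6%. The forestomach controls 2, 3 and 5 stood at 98.6%, 48.5% and 67.2%, and the libraries labelled knock-in 1, 2 and 4 at 70.5%, 60.4% and 79.3%. Between 9248 and 12387 genes per library had an FPKM of at least 1.

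The housekeeping gene Gapdh, a glycolytic enzyme, had a mean of 171 ± 16.5 FPKM in hindstomach controls (SD, n = 3) and 41.0 ± 55.9 in knockout libraries (n = 5). Its mean was 104 ± 95.9 FPKM in forestomach controls (n = 3) and 9.25 ± 11.8 in the libraries labelled knock-in (n = 3). Across genes the deviations of the libraries followed the GC content of the transcripts, and whether this accounts for the spread of Gapdh was not tested. The slope of centred log2(FPKM + 1) per 10% GC was 0.579 ± 0.026 in hindstomach controls and -0.186 ± 0.461 in knockout libraries. In forestomach controls it was 0.275 ± 0.772, with a slope of -0.609 in replicate 5 alone below 0, and in the libraries labelled knock-in it was -0.544 ± 0.399. The first principal component held 66.3% of the variance, and across genes its loadings correlated with GC content at 0.691. Across libraries its scores correlated with the GC slope at 0.99 in absolute value. The slope thus nearly equals the main component of the same values, and passing with it as a covariate is no independent check. Slopes on transcript length mostly had the opposite sign, so this axis cannot be assigned to GC content alone. Gene counts of each group are therefore given also with the slope as a covariate, an alternative chosen after the data were examined.

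**Figure D1:**
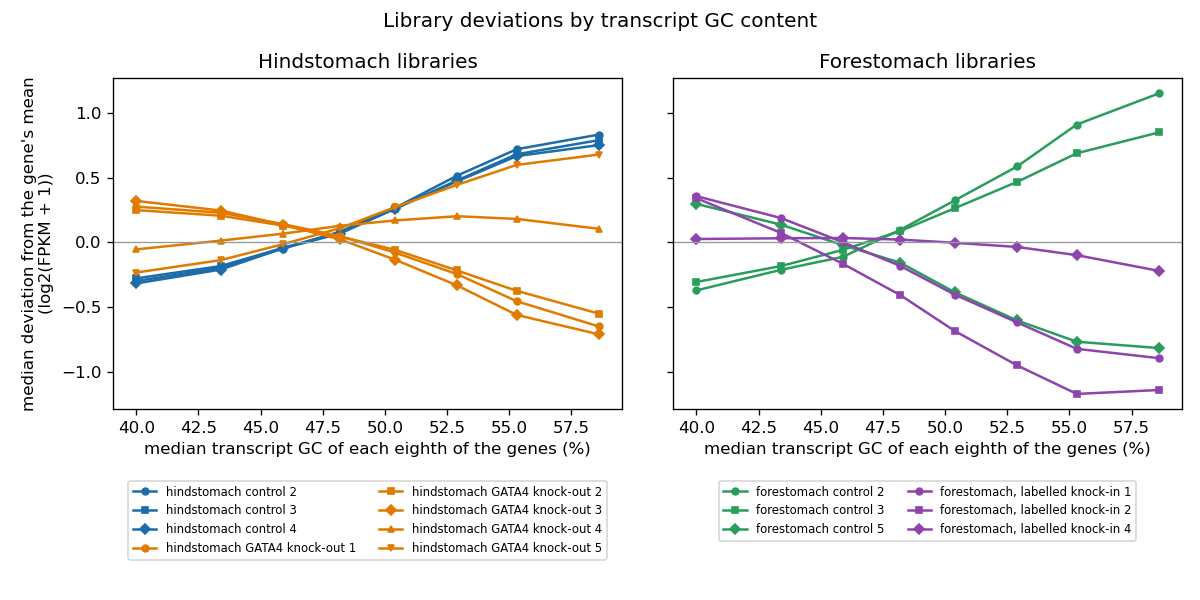
Median deviation of each library from the gene means, in log2(FPKM + 1), against the median transcript GC content (%) of each eighth of the genes, with 1 line per library. Lines of the 3 hindstomach controls rose with GC content, with slopes of 0.563 to 0.609 per 10% GC, whereas knockout replicates 1 to 3 and forestomach control 5 (slope -0.609) fell with it.

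Gata4, the targeted gene, was measured at 64.0 ± 2.19 FPKM in hindstomach controls (SD, n = 3) and 28.2 ± 19.0 FPKM in knockout libraries (n = 5). The libraries labelled knockout 1 to 5 held 16.87, 19.36, 13.02, 32.06 and 59.63 FPKM, each below the lowest control (61.55). At 59.63 FPKM the last of them stood near control level, so Gata4 did not bear out its label, and it is named below as the library labelled knockout 5. Across these 5 libraries, however, Gata4 rose in step with the GC slope, which was -0.52, -0.42, -0.57, 0.09 and 0.49 in 1 to 5. The slope of knockout 5 was thus near those of the hindstomach controls (0.563 to 0.609), and its Gata4 level cannot be told apart from the slope. The log2 fold change of Gata4 was -1.37 (SE 0.47), with a limma adjusted p of 0.0672 and an exact two-sided permutation p of 0.0357 over 56 splits. In the forestomach Gata4 stood at 4.50, 1.33 and 0.57 FPKM in the controls and at 0.40, 0.32 and 1.27 FPKM in the libraries labelled knock-in. That log2 fold change was -0.75 (SE 0.53, limma adjusted p = 0.268, exact permutation p = 0.2, where 20 splits allow no p below 0.1). Gata4 thus went against the knock-in label, and every direction given below for these libraries rests on the label alone. The labels do not say which exons were removed or how the added copy was built, so the FPKM of the whole gene is no direct measure of either. The Gata4 fold changes were -0.38 (adjusted p = 0.354) and 0.30 (adjusted p = 0.555) with the slope covariate, so with it Gata4 bore out the label of neither mutant group.

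The paralogs Gata5 and Gata6 both fell in the knockout libraries, with log2 fold changes of -1.67 (SE 0.43, adjusted p = 0.0269) and -1.0 (SE 0.28, adjusted p = 0.0381). The Gata5 call ended with the slope covariate (-0.89, adjusted p = 0.0841), whereas Gata6 still passed (-1.12, adjusted p = 0.0414). In the libraries labelled knock-in Gata5 differed by 0.67 (adjusted p = 0.285), which passed with the slope covariate (1.5, adjusted p = 0.0294), and Gata6 by -0.87 (adjusted p = 0.0959). All 3 Gata genes were higher in control hindstomach than in control forestomach, Gata4 by 4.58 (SE 0.53, adjusted p = 8.41e-05), Gata5 by 3.14 (SE 0.48, adjusted p = 0.000642) and Gata6 by 1.60 (SE 0.32, adjusted p = 0.00335).

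**Figure D2:**
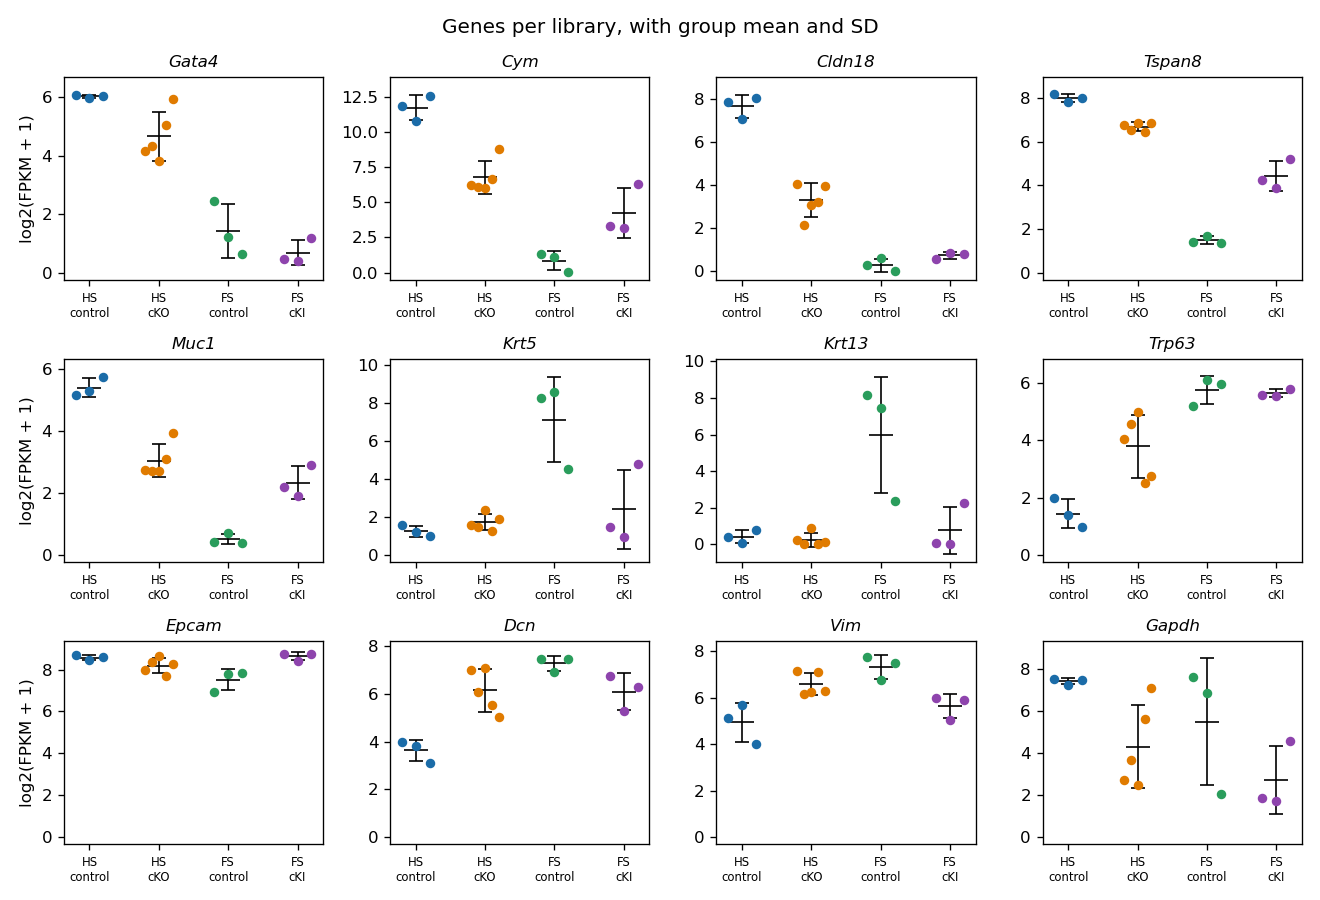
log2(FPKM + 1) of 12 genes in each library (points), with the mean and SD of each group (HS, hindstomach, FS, forestomach, cKO, labelled knockout, cKI, labelled knock-in). Gata4 lay at 0.32 to 1.27 FPKM in the libraries labelled knock-in against 61.6 to 65.7 FPKM in hindstomach controls, and Cldn18 averaged 9.89 FPKM in knockout libraries against 206 FPKM in their controls.

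Control hindstomach and control forestomach differed in the markers of their own epithelia. Cym, the milk-clotting protease chymosin, was higher in hindstomach by 10.87 on the log2 scale (SE 0.88, adjusted p = 7.99e-06), Cldn18, the stomach claudin, by 7.34 (SE 0.43, adjusted p = 5.89e-07) and the tetraspanin Tspan8 by 6.52 (SE 0.27, adjusted p = 4.07e-08). Akr1c19, Habp2, Agr2, Anxa10 and Sult1d1, the other genes with the largest differences, were higher by 5.59 to 5.80. Lower in hindstomach were the squamous keratins Krt5 (-5.88, SE 1.03, adjusted p = 0.00153), Krt13 (-5.56, SE 1.15, adjusted p = 0.00444) and Krt15 (-5.05, SE 1.09, adjusted p = 0.00561). Trp63, the transcription factor of basal squamous cells, stood at -4.30 (SE 0.57, adjusted p = 0.000235), and Dapl1, Serpinb5, Lum and Cav1 at -4.89 to -4.21. In total 1231 genes were higher in hindstomach and 1352 higher in forestomach among 12694 tested, and all 2583 also passed in the same direction with the slope covariate, which called 5325.

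By list, 20 of 30 measured glandular genes were higher in control hindstomach and 2 lower (Krt20 and Cldn10), with 22 and 3 adjusted over the list alone (camera adjusted p = 1.33e-13, and adjusted p = 0.0959 with an estimated correlation). Of 31 squamous genes 21 were higher in forestomach and 2 lower (Capn6 and Fermt1), with 25 and 3 adjusted over the list alone (camera adjusted p = 3.44e-12, and adjusted p = 0.0959 with an estimated correlation). The AP-2 factor Tfap2c stood at -3.38 and the zinc-finger factor Bnc1 at -2.70. Parietal and chief cell genes (7 of 8 higher in hindstomach, also adjusted over the list alone, adjusted p = 1.05e-06, and 0.122 with an estimated correlation) included Atp4b, the beta subunit of the gastric proton pump, at 5.29. Tight junction genes (10 of 21, adjusted p = 1.29e-05), microvillus genes (7 of 14, adjusted p = 6.36e-05), intestinal genes (3 of 5, adjusted p = 6.36e-05) and enteroendocrine genes (4 of 9, adjusted p = 0.00744) were also higher in hindstomach, and with an estimated correlation their adjusted p were 0.135, 0.122, 0.0959 and 0.169. Adjusted over the list alone 14, 7, 5 and 4 of them were higher. Given the slope covariate, 24 glandular, 7 parietal and chief cell, 15 tight junction, 8 microvillus, 5 intestinal and 4 enteroendocrine genes were higher in hindstomach and 26 squamous genes in forestomach.

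Markers of cells outside the epithelium differed between the control regions as well. Mesenchyme genes were higher in forestomach for 20 of 26 (22 adjusted over the list alone, median -2.36, camera adjusted p = 6.34e-14), with Dcn at -3.66 and Twist1 at -3.08. Mesothelium genes were higher there for 8 of 9 (median -2.74, adjusted p = 1.03e-06), with Wt1 at -3.73, and smooth muscle genes for 6 of 11 (median -2.49, adjusted p = 1.58e-05). Leukocyte genes (4 of 15, adjusted p = 0.00051), endothelial genes (2 of 8, adjusted p = 0.00849) and enteric neuron and glia genes (1 of 15, Hand2, adjusted p = 0.0065) followed, whereas red blood cell genes did not pass as a list (adjusted p = 0.184). With an estimated correlation none of these lists passed, with adjusted p of 0.122 for mesenchyme, 0.0959 for mesothelium, 0.179 for smooth muscle, 0.356 for leukocytes, 0.384 for endothelium and 0.426 for enteric neurons and glia. Adjusted over the list alone the counts were 8 mesothelium, 9 smooth muscle, 4 leukocyte, 5 endothelial and 0 enteric genes. The slope covariate raised most counts over all genes, to 25 mesenchyme, 8 mesothelium, 11 smooth muscle, 12 leukocyte, 6 endothelial, 7 enteric and 2 red blood cell genes higher in forestomach.

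Signalling lists also parted the control regions. Of the BMP list 5 of 16 genes were higher in forestomach (6 adjusted over the list alone, adjusted p = 0.00128, and 0.0959 as adjusted p with an estimated correlation), with the ligand Bmp4 at -2.87 and its antagonist follistatin, Fst, at -3.99. In the Wnt list 8 of 19 genes were higher in forestomach (10 adjusted over the list alone, adjusted p = 0.00635, and 0.141 with an estimated correlation), among them Lef1 (-1.97), and 3 were higher in hindstomach, Fzd5 (4.03), Lgr5 (2.99) and Lgr4 (1.22). Of the Notch list 6 of 15 were higher in forestomach (7 adjusted over the list alone, adjusted p = 0.0115, and 0.141 with an estimated correlation), including Nrarp at -1.38. The Hedgehog list did not pass (adjusted p = 0.0647, and 0.0281 with the slope covariate, where an estimated correlation gave 0.317), although Ihh was higher in hindstomach by 4.68 (SE 0.63, adjusted p = 0.000269). Cholesterol synthesis genes were higher in hindstomach as a list (2 of 20 called and 1 adjusted over the list alone, median 0.728, adjusted p = 0.00494, and 0.361 with an estimated correlation). Stress genes such as Fos (-1.90) were higher in forestomach for 4 of 14 (4 adjusted over the list alone, adjusted p = 0.0115, and 0.436 with an estimated correlation). Under the slope covariate 9 BMP, 12 Wnt, 7 Notch, 7 Hedgehog and 7 stress genes were higher in forestomach and 11 cholesterol genes in hindstomach.

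In the hindstomach labelled knockout, genes of the gastric glandular epithelium fell. Cldn18 fell by 4.34 on the log2 scale (SE 0.39, adjusted p = 0.000134), from 206 ± 66.2 FPKM in controls (SD, n = 3) to 9.89 ± 5.18 in knockout libraries (n = 5). Cym fell by 4.95 (SE 0.79, adjusted p = 0.00295), from 3759 ± 2093 to 150 ± 166 FPKM. Atp4b fell by 5.24 (SE 0.24, adjusted p = 1.72e-07), from 41.5 ± 22.3 to 0.0302 FPKM. Bpifb1, Apoa1, Sult1d1, Clps and Anxa10 fell to log2 fold changes of -4.54 to -3.94, and all 8 of these genes also passed with the slope covariate. Of 30 measured glandular genes 19 fell and 2 rose, the claudin Cldn10 (2.15) and the keratin Krt20 (1.47), with 21 and 2 adjusted over the list alone (camera adjusted p = 4.34e-10, and 0.411 as adjusted p with an estimated correlation). The trefoil peptide gene Tff2 (-3.05), the pepsinogen gene Pgc (-3.73), the mucin Muc1 (-2.36) and the gastrokine Gkn3 (-1.86) were among those that fell. With the slope covariate the glandular counts were 19 and 2 again, and the list called the same 19 genes as fallen and the same 2 as risen.

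Genes of polarised columnar cells and of parietal and chief cells fell as well in the knockout libraries. Of the parietal and chief cell list 6 of 8 fell (7 adjusted over the list alone, camera adjusted p = 6.74e-06), among them the pepsinogen gene Pga5 (-3.70) and the potassium channel subunit Kcne2 (-2.59), and 1 rose, Slc26a7 (0.90). Of the tight junction list 9 of 21 fell and 0 rose (13 and 2 adjusted over the list alone, adjusted p = 0.00443), including Crb3 (-1.38) and Marveld2 (-0.99). Of the microvillus list 8 of 14 fell, such as the brush border myosin Myo1a (-2.43) and Espn (-2.18), and Cobl (0.77) and Cdh17 (0.87) rose (9 and 2 adjusted over the list alone, adjusted p = 0.00415). With an estimated correlation the adjusted p was 0.411 for each of these 3 lists, and with the slope covariate 6, 7 and 6 of their genes fell, 6 of each list in both fits. Slc26a7 no longer passed with the covariate (0.82, adjusted p = 0.0987). The pan-epithelial gene Epcam did not pass (-0.39, adjusted p = 0.231), at 382 ± 30.2 FPKM in controls and 298 ± 72.9 in knockout libraries. Apoa1 (-4.38) and Anpep (-3.15) were the 2 of 5 intestinal genes that fell, and that list did not pass (adjusted p = 0.0794), although it did with the slope covariate (adjusted p = 0.00256, and 0.222 with an estimated correlation).

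Genes higher in the knockout libraries included markers of the forestomach and of mesenchyme. Trp63 rose by 2.34 (SE 0.51, adjusted p = 0.0145), from 1.83 ± 1.02 to 15.9 ± 11.1 FPKM, with Bnc1 at 1.20 and Gata3 at 0.80, whereas Krt5 (0.47, adjusted p = 0.70) and Krt13 (-0.17, adjusted p = 0.903) did not pass. Of 31 squamous genes 4 rose and 1 fell, Fermt1 (-1.04), with 4 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.102), although it did with the slope covariate (7 rose, 0 fell, adjusted p = 0.0105, and 0.57 with an estimated correlation). Dcn, a collagen-binding proteoglycan of fibroblasts, rose by 2.52 (SE 0.47, adjusted p = 0.00728), from 11.8 ± 3.64 to 81.4 ± 47.9 FPKM. Ogn, Cav1, Lum, Sema3d, Mest, Sfrp1 and Hoxa4 rose by 2.36 to 2.58, of which Lum did not pass with the slope covariate (1.87, adjusted p = 0.109). Of 26 mesenchyme genes 15 rose and 0 fell (17 adjusted over the list alone, median 1.43, adjusted p = 8.2e-09). Enteric neuron and glia genes rose for 7 of 15 (10 adjusted over the list alone, median 1.20, adjusted p = 2.22e-05), and mesothelium genes rose for 4 of 9 with Msln falling by 3.06 (5 and 1 adjusted over the list alone, adjusted p = 0.00984). With an estimated correlation the adjusted p was 0.411 for these 3 lists. With the slope covariate 14, 8 and 5 of their genes rose, of which 9, 5 and 3 had also risen without it. The mesothelium call was lost without the library labelled knockout 5.

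Other lists did not pass as sets in the knockout comparison with FPKM as deposited, and 4 of them passed with the slope covariate. These were smooth muscle (8 of 11 risen adjusted over the list alone, camera adjusted p = 0.000847), leukocytes (5 of 15, adjusted p = 0.00535), Hedgehog (8 of 14 with 2 fallen, adjusted p = 0.013) and cell cycle (1 of 29, adjusted p = 0.00256), all placed up. An estimated correlation in that fit gave 0.452, 0.57, 0.419 and 0.561. As deposited, smooth muscle had 2 risen genes, Mylk (1.69) and Synpo2 (1.57), while endothelium, red blood cell and leukocyte lists had 0 (camera adjusted p = 0.0794, 0.179, 0.863 and 0.104). In the Hedgehog list Gas1 (2.14), Gli3 (1.19), Cdon (0.87) and Hhip (0.84) rose and the ligand Ihh fell by 2.48, a call lost with the slope covariate (-1.65, adjusted p = 0.0549). Among the FGF genes Fgf10 rose (1.95) and Fgf20 fell (-1.55), among the Wnt genes Sfrp1 rose (2.44) and Fzd5 fell (-1.24), and among the Notch genes Hey1 rose (1.62). Of the BMP list Bmp2 (-1.13) and Msx2 (-0.84) fell and Fst (1.70) and Id2 (1.10) rose. The enteroendocrine genes Scg3 (1.68) and Rfx6 (0.70), the cell cycle genes Mki67 (0.57) and Kif11 (0.58), 2 of 10 desmosome genes (Jup at -2.36 and Dsc2 at -1.22), the liver and pancreas gene Ttr (-1.86) and the stress gene Ier2 (-1.04) passed, and 0 of 16 hemidesmosome and 0 of 20 cholesterol synthesis genes did. Besides Ihh, 10 of these genes no longer passed with the slope covariate. Their folds were then 1.56 for Mylk, 1.16 for Synpo2, 0.61 for Hhip, 1.25 for Fst, 0.66 for Id2, 0.66 for Rfx6, 0.32 for Mki67, 0.27 for Kif11, -1.28 for Ttr and -0.51 for Ier2, so Mylk and Rfx6 kept most of their size and Kif11 and Ier2 did not. Jup still passed, at -0.68. As deposited, the camera adjusted p ranged from 0.102 to 0.933 over the Hedgehog, Wnt, Notch, BMP, FGF, retinoic acid, enteroendocrine, cell cycle, cholesterol, desmosome, hemidesmosome, liver and stress lists.

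In total 883 genes rose and 797 fell in the knockout libraries, and 961 and 594 with the slope covariate. Of these, 448 rose and 498 fell in both fits, and 0 genes were called in opposite directions. Genes that rose had a median GC content of 45.6% and genes that fell 53.1%, against 49.3% among all tested genes. Rescaling each library to a common FPKM sum gave 1359 risen and 520 fallen genes, with the median of all genes at 0.182 in place of -0.083. The count was 4124 without the library labelled knockout 5 and 267 without hindstomach control 4.

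In the forestomach libraries labelled knock-in, some hindstomach genes (158 of the 1231 higher in control hindstomach) rose and some squamous genes (13 of 31) fell, although Gata4 itself was not higher. Vsig1, a stomach junction protein, rose by 2.95 (SE 0.26, adjusted p = 0.000127), from 0.532 FPKM in controls to 10.5 ± 0.395 (SD, n = 3). Tspan8 rose by 2.96 (SE 0.27, adjusted p = 0.000163), from 1.82 ± 0.361 to 22.6 ± 11.9 FPKM, and Lgr5, a Wnt co-receptor and stem cell marker, by 3.38 (SE 0.21, adjusted p = 6.83e-06), from 0.204 to 11.6 ± 1.79 FPKM. Nup62cl, Akr1c19, Spon1 and Itih2 rose by 3.02 to 3.57 and Cym by 3.39 (SE 0.88, adjusted p = 0.0453), and all 8 also passed with the slope covariate. The squamous keratin Krt13 fell by 5.22 (SE 1.15, adjusted p = 0.0289), from 155 ± 142 to 1.25 ± 2.13 FPKM, and Krt6a stood at -3.46 (SE 0.48, adjusted p = 0.00262). Pkp1, Col17a1, Anxa8, Krtdap, Zfp750 and Fabp4 fell by 2.62 to 3.09, and with the slope covariate Krt13 (-3.30, adjusted p = 0.0549) and Pkp1 (-2.24, adjusted p = 0.0535) no longer passed.

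By list, 13 of 31 squamous genes fell in the libraries labelled knock-in and 2 rose, Capn6 (1.35) and Pax9 (1.09), with 21 and 4 adjusted over the list alone (median -1.32, camera adjusted p = 0.00384, and 0.537 as adjusted p with an estimated correlation). The homeobox gene Dlx3 (-2.06), Gata3 (-1.60) and the desmosomal cadherin Dsg3 (-1.91) were among those that fell, as were Krt5 (-4.72) and Krt15 (-4.68), whereas Trp63 did not pass (-0.10, adjusted p = 0.897). In the fit with the slope covariate 7 squamous genes fell and 1 rose, and Krt5 (-3.03, adjusted p = 0.0534) and Krt15 (-2.69, adjusted p = 0.0573) were not among them. Of 30 glandular genes 6 rose and 0 fell, also adjusted over the list alone (median 0.123, adjusted p = 0.00112, and 0.531 with an estimated correlation), among them Muc1 (1.83), and 9 rose with the slope covariate, while Cldn18 did not pass (0.45, adjusted p = 0.414). The tight junction list passed (adjusted p = 0.00467, and 0.531 with an estimated correlation) with 1 of 21 genes risen, Ocln (1.56), and 4 adjusted over the list alone, a list call lost without forestomach control 5. Single risen members of other columnar lists were Hnf4g (1.32), Prom1 (0.99), Esrrg (2.11), Ddc (1.02) and the desmosomal Pkp2 (1.07), whereas Slc26a7 of the parietal and chief cell list (-1.14) and Dsg3 and Pkp1 of the desmosome list fell. The Slc26a7 call was lost with the slope covariate (-1.23, adjusted p = 0.0526), with a fold of about the same size. The desmosome, hemidesmosome, microvillus, intestinal, parietal and chief cell and enteroendocrine lists did not pass (adjusted p = 0.343, 0.634, 0.343, 0.0588, 0.128 and 0.166). The intestinal list alone of these passed with the slope covariate (adjusted p = 0.0206, and 0.321 with an estimated correlation). Epcam rose by 1.11 (SE 0.27, adjusted p = 0.0393), from 190 ± 59.8 to 398 ± 49.8 FPKM, a call lost with the slope covariate (0.89, adjusted p = 0.0859).

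Of 7 lists of cells outside the epithelium 5 passed as lower in the libraries labelled knock-in, with few single genes called. Mesenchyme genes fell for 4 of 26 (19 adjusted over the list alone, median -1.43, adjusted p = 4.81e-05), including Col1a1 (-2.16), Sparc (-1.75) and Vim (-1.68). Mesothelium genes fell for 6 of 9 (8 adjusted over the list alone, median -1.69, adjusted p = 0.00112), including Upk1b (-2.20) and Podxl (-1.69). Over all genes 0 smooth muscle and 0 red blood cell genes passed limma, whereas 10 and 8 did adjusted over the list alone, and both lists passed camera (medians -1.85 and -2.47, adjusted p = 0.00225 and 0.00697). The leukocyte list passed with 1 of 15 genes fallen, Aif1 at -1.26 (3 adjusted over the list alone, adjusted p = 0.00742), while the endothelium and enteric lists did not (adjusted p = 0.0566 and 0.0588). With an estimated correlation the adjusted p was 0.531 for the mesenchyme, mesothelium, smooth muscle and red blood cell lists and 0.562 for leukocytes. In the fit with the slope covariate 2 mesenchyme, 5 mesothelium, 0 smooth muscle, 0 red blood cell and 1 leukocyte genes fell, of which 0, 4, 0, 0 and 1 had also fallen without it. Col1a1 (-1.66, adjusted p = 0.051), Sparc (-1.44, adjusted p = 0.0848) and Vim (-1.64, adjusted p = 0.0789) no longer passed there, whereas the endothelium and enteric lists passed camera (adjusted p = 0.0319 and 0.0123, and 0.541 for both with an estimated correlation). Without forestomach control 5 the mesothelium, red blood cell and leukocyte calls were lost.

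Cell cycle and cholesterol synthesis genes stood above other genes in the libraries labelled knock-in. Top2a (0.84), Kif11 (1.03) and Cenpf (0.87) were among 6 of 29 cell cycle genes that rose (8 adjusted over the list alone), and camera placed the list up (adjusted p = 0.00384) although its median was -0.16 and its mean -0.04. The sterol enzymes Idi1 (1.28), Msmo1 (1.11) and Sc5d (0.85) were among 5 of 20 cholesterol genes that rose (8 adjusted over the list alone), and camera placed that list up (adjusted p = 0.00486) with a median of -0.0232 and a mean of -0.134. The median of all tested genes was -0.371. Of the BMP list 3 of 16 genes fell, Id3 (-2.26), Bmp4 (-1.78) and Id1 (-1.77), with 6 adjusted over the list alone (adjusted p = 0.0348), and Fos (-1.07) was among 3 of 14 stress genes that fell, with 8 adjusted over the list alone (adjusted p = 0.00697). With an estimated correlation the adjusted p was 0.531 for the cell cycle, cholesterol and BMP lists and 0.562 for the stress list. Given the slope covariate, 3 cell cycle and 6 cholesterol genes rose, and 5 BMP and 0 stress genes fell. Of these, 2 cell cycle, 5 cholesterol and 2 BMP genes had also been called without it. Cenpf (0.52, adjusted p = 0.0505) and Id1 (-1.08, adjusted p = 0.0707) no longer passed there, and Id3 passed at -1.24. These 4 list calls were lost without forestomach control 5 and with quantile normalization, and the BMP and cholesterol calls also after rescaling to a common FPKM sum. In the Wnt list Wif1 (-1.63) was among 4 that fell and Lgr4 (1.12) among 3 that rose, and the Wnt, Hedgehog, Notch, FGF, retinoic acid and liver lists did not pass (adjusted p = 0.873, 0.117, 0.634, 0.631, 0.166 and 0.634).

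In total 333 genes rose and 409 fell in the libraries labelled knock-in, and 320 and 376 with the slope covariate, of which 202 rose and 184 fell in both fits. Genes that rose had a median GC content of 44.2% and genes that fell 51.7%. Rescaling to a common FPKM sum gave 567 risen and 146 fallen genes, with the median of all genes at -0.0517, and quantile normalization gave 368 and 121, with the median at 0.0752. In a limma fit of these 6 libraries alone 0 genes passed, with 1932 at an unadjusted p under 0.05, and the count was 7015 without forestomach control 5 and 118 without forestomach control 2.

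**Figure D3:**
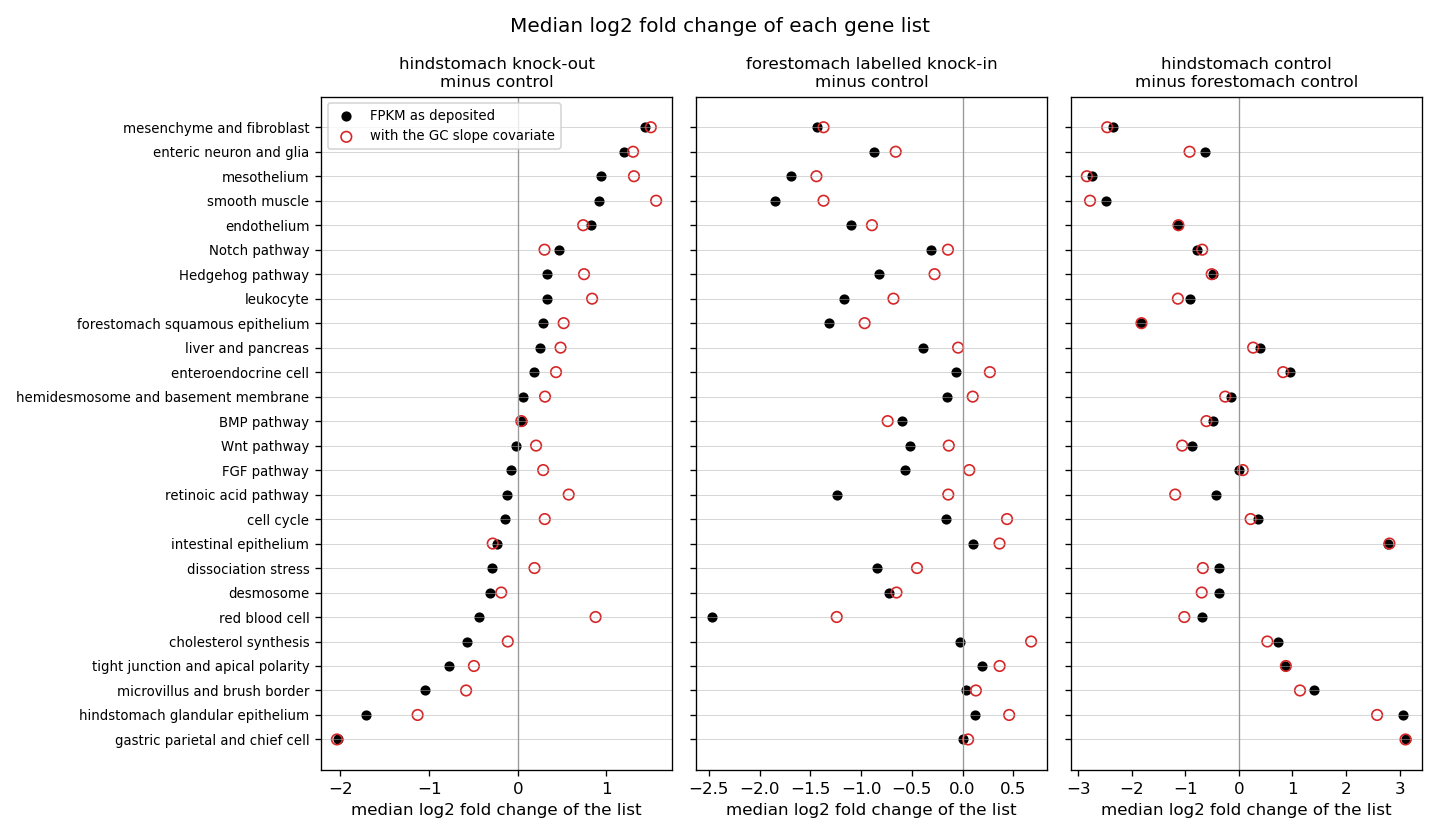
Median log2 fold change of each gene list in the 3 comparisons, with FPKM as deposited (filled) and with the slope of each library on transcript GC as a covariate (open). The glandular list had medians of -1.71 in knockout libraries and 3.07 between control regions, and the squamous list -1.32 in the libraries labelled knock-in.

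Genes that went in opposite directions in the mutant groups included hindstomach genes such as Cym. Cym fell in knockout libraries and rose in the libraries labelled knock-in (-4.95 and 3.39), as did the nuclear receptor Esrrg (-2.32 and 2.11), Muc1 (-2.36 and 1.83), Arl14 (-2.02 and 2.54), Cfi (-2.44 and 1.96) and Habp2 (-1.96 and 2.30). Ccl11 (1.76 and -2.40), Hoxa4 (2.36 and -1.70), Vim (1.66 and -1.68) and Sparc (1.44 and -1.75) rose in the former and fell in the latter. The slope covariate kept both calls of Hoxa4 alone among these 4, since Ccl11 (1.60 and -2.57, adjusted p = 0.113 and 0.0502) and the knock-in calls of Vim (-1.64, adjusted p = 0.0789) and Sparc (-1.44, adjusted p = 0.0848) were lost, with folds of about the same size. In total 47 genes fell in knockout libraries and rose in the libraries labelled knock-in, where independent lists would share 20.9 (one-sided exact hypergeometric p = 1.32e-07), and 64 rose and fell, 2 of them on the mesenchyme list (Sparc and Vim), where 28.5 would be shared (exact p = 5.81e-10). Both p-values treat genes as independent draws, although genes move together and both lists come from the same fit. They therefore measure no spread between libraries and are likely too small. In the same direction 20 genes fell in both and 19 rose in both, including Cldn10, against 25.7 and 23.2. With the slope covariate the opposite counts were 75 and 90 and the same-direction counts 15 and 5.

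Across the 12694 genes the knockout and knock-in fold changes had a Pearson correlation of 0.478, a value across genes, which are not independent replicates. It was -0.382 with the slope covariate.

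**Figure D4:**
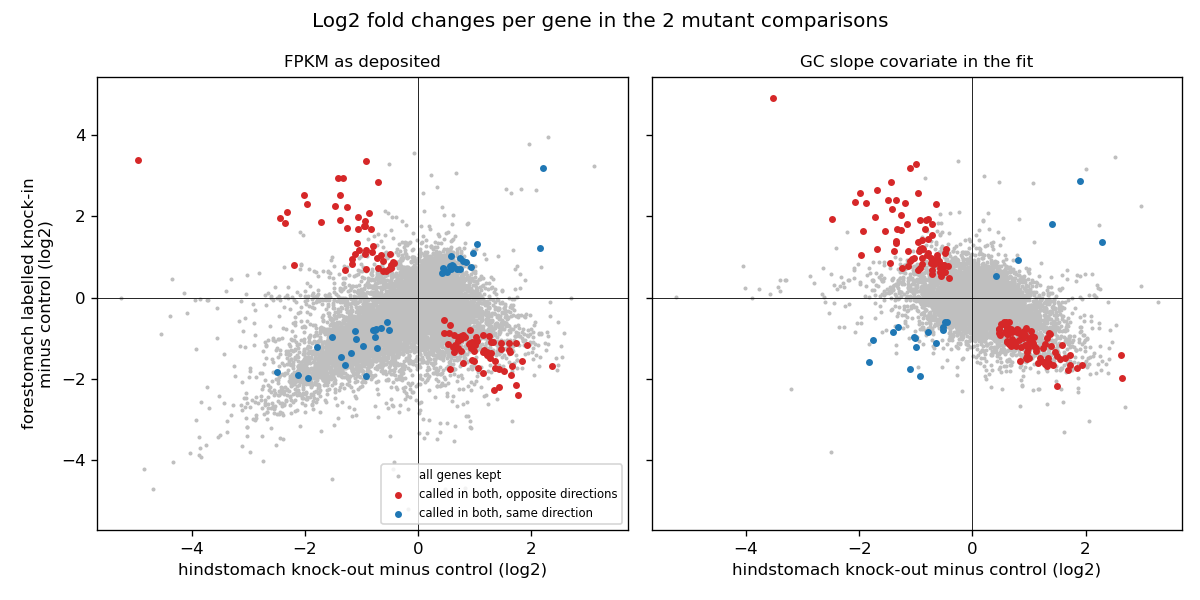
Log2 fold change in the libraries labelled knock-in against that in knockout libraries, 1 point per gene, with FPKM as deposited and with the GC slope covariate. Red genes were called in opposite directions and blue genes in the same direction. The correlation was 0.478 in the former panel and -0.382 in the latter.

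Genes that differed between the control regions were set against the mutant calls. Among genes higher in control hindstomach, such as Cldn18 and Cym, 454 fell in knockout libraries and 3 rose, and among genes higher in control forestomach, such as Trp63 and Dcn, 503 rose and 2 fell. In the libraries labelled knock-in 158 hindstomach genes such as Vsig1 rose and 8 fell, and 260 forestomach genes such as Krt13 fell and 5 rose. These 957 and 418 genes made up 57.0% and 56.3% of the calls. Independent lists would share 171 and 75.9 genes, and 50 simulated groups without any effect against the same controls gave a median of 0, with a highest value of 182 for the knockout and 6609 for the knock-in comparison. The real knockout count was reached by 0 of 50 simulations and the real knock-in count by 8 of 50, so the latter is not set apart from what shared controls alone give. With the slope covariate 1190 and 576 genes moved toward the other region, 76.5% and 82.8% of the calls, and 0 of 50 and 1 of 50 simulations reached these counts (highest 456 and 903). With 3 controls per region no split into parts of at least 2 libraries was possible. Regional genes also included markers of cells outside the epithelium, such as Dcn. The mesenchyme list had medians of -2.36 between control regions, 1.43 in knockout libraries and -1.43 in the libraries labelled knock-in. A different share of such cells could move these genes the same way, so the counts do not measure a change of the epithelium alone.

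A score per library, the mean log2 level of the squamous list minus that of the glandular list, placed every mutant group between the control regions. It was -2.75 ± 0.249 in hindstomach controls (SD, n = 3), -0.77 ± 0.438 in knockout libraries (n = 5), 0.56 ± 0.072 in the libraries labelled knock-in (n = 3) and 2.29 ± 0.371 in forestomach controls (n = 3). The knockout difference was 1.98 (exact two-sided permutation p = 0.0179 over 56 splits) and the difference of the libraries labelled knock-in was -1.73 (exact permutation p = 0.1, the smallest that 20 splits allow). The control regions differed by -5.04 (exact permutation p = 0.1). After a GC spline was removed from each library these differences were 1.86, -1.86 and -4.98. The knockout difference came mostly from loss of glandular genes (mean log2 fold change -1.8, against 0.18 for squamous genes), and the other from loss of squamous genes (-1.49, against 0.24 for glandular genes). An intermediate score is thus no measure of a gain of the other region's genes.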

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

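The gap test was fixed before its results were seen, and the comparison of 1 library with a control left out of the choice of genes was chosen afterwards.

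In the group of 5 knockout libraries 36 values were tested for a library far from the others, with Dixon's gap ratio and a critical value of 0.71. Chance marks about 1 in 20 such groups. Cym exceeded it with a log2(FPKM + 1) of 8.8 in the library labelled knockout 5 (ratio 0.767), Apoa1 with 2.1 (ratio 0.775) and Clps with 3.08 (ratio 0.768), so all 3 came from the same library and were not independent. Gata4 in that library stood at 59.63 FPKM, close to its controls, and so did not bear out the label. The GC slope of that library (0.49) was also close to its controls, so this Gata4 level cannot be told apart from the slope. The score of squamous minus glandular genes in that library, from lists fixed beforehand, was -1.44. It lay above the controls (-2.96 to -2.48) and below the other knockout libraries (-0.951 to -0.333). Genes that fell without this library and without 1 control in turn lay below that control in it for 97%, 92.1% and 95.5% (642, 1140 and 575 genes), and for 98.5%, 94% and 98.3% with the GC slope covariate. Another control would give 50% on average, but such genes move together, so a single control could also lie far from 50%. The median differences of these genes from the control left out were -0.66, -0.36 and -0.70, against -1.53, -1.33 and -1.66 in the other knockout libraries. The 3 turns share libraries and are not independent. These values rest on 1 library against 3 controls and do not settle whether it is a control library. The cause of the smaller change was not tested.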

How the results depend on the processing

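The corrections for GC content, transcript length and the residual component were chosen after the data were examined, and the other alternatives before.

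Gene counts are given as knockout, knock-in and regional comparison where 3 stand together. The count was 941, 445 and 1661 at an FPKM of at least 5, where fewer genes were tested, 961, 442 and 1680 at a 2-fold minimum, and 9688, 10680 and 5870 with array weights. In fits of the compared groups alone it was 4991, 0 and 1431, with fewer libraries behind each spread and 1932 knock-in genes at an unadjusted p under 0.05. Quantile normalization gave 489 knock-in genes. The GC covariate gave 5325 regional genes, a GC spline removed per library gave 2655, 1332 and 4027, libraries of one GC slope sign gave 579 and 108 (fewer samples, with forestomach control 5 alone assumed to vary like the others), the length covariate gave 834, 260 and 6184, and the residual component gave 7838, 7893 and 7085. These 5 corrections disagree, and the cause of each shift other than fewer genes or samples was not tested.

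Genes that fell in knockout libraries and rose in those labelled knock-in, and those that rose and fell, numbered 250 and 813 with array weights, 127 and 106 with the spline, 16 and 9 with one slope sign, 152 and 616 with the residual component, 19 and 32 at a 2-fold minimum, and 0 and 0 in fits of the compared groups alone. The former alone moved to 75 with the GC covariate, and the latter alone to 40 at a pseudocount of 0.1, 29 at FPKM 5, 32 after rescaling, 21 after quantile normalization and 20 with the length covariate. Regional genes moved by the knockout and by the knock-in numbered 592 and 228 at FPKM 5, 3281 and 3023 with array weights, 1581 and 730 with the spline, 396 and 73 with one slope sign, 4781 and 1926 with the residual component, and 582 and 261 at a 2-fold minimum. For the knock-in alone they numbered 271 after quantile normalization, 0 in the fit of the compared groups and 218 with the length covariate.

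The correlation of fold changes was 0.441 at a pseudocount of 0.1, 0.542 at FPKM 5, 0.695 with array weights and 0.18 with the spline, and it reversed to -0.382 with the GC covariate, -0.419 with one slope sign and -0.377 with the length covariate. Gata4 in the libraries labelled knock-in reversed to 0.30 and 0.036 with the GC covariate and with one slope sign, neither past the threshold. Hspb1 in knockout libraries, at -0.43, reversed to 1.69 with the GC covariate (adjusted p = 0.0199) and 0.24 with one slope sign. The score difference moved to -2.58 and -2.09 in the knock-in and to -7.12 and -6.02 in the regional comparison at a pseudocount of 0.1 and after rescaling. Within the GC covariate fit, the rose-and-fell count was 57 at a pseudocount of 0.1 and 50 at FPKM 5, the knockout count 837 and its regional genes 665 at FPKM 5, and the correlation -0.336 after quantile normalization.

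Leaving out each library in turn, the knockout count ranged from 267 to 4124, the knock-in count from 118 to 7015 and the regional count from 1532 to 2680. The knockout count was 337 without hindstomach control 2, 1113 without control 3 and 267 without control 4, and 750, 1004, 802, 990 and 4124 without the libraries labelled knockout 1 to 5. The knock-in count was 118, 329 and 7015 without forestomach controls 2, 3 and 5, and 120, 126 and 3283 without the libraries labelled knock-in 1, 2 and 4. The regional count was 1532 without hindstomach control 4. The fell-and-rose count ranged from 14 to 84, the rose-and-fell count from 4 to 252, regional genes from 223 to 1432 (knockout) and 88 to 1102 (knock-in), the correlation from 0.353 to 0.594, and the score differences from 1.87 to 2.15, -1.92 to -1.55 and -5.23 to -4.86. With the GC covariate the ranges were 385 to 2341, 84 to 1348 and 3627 to 5253 for the counts, 14 to 100 and 2 to 158 for the opposite genes, 323 to 1605 and 79 to 1117 for regional genes, and -0.403 to -0.266 for the correlation. There the knockout count was 563 and 385 without hindstomach controls 2 and 4 and 708 and 2341 without the libraries labelled knockout 4 and 5, and the knock-in count 1348 and 84 without forestomach controls 3 and 5 and 1178 without the library labelled knock-in 4.

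With the replicate number as a replicate block, 644 knockout and 1284 regional genes were called. The deviations of same-numbered hindstomach libraries 2, 3 and 4 correlated at 0.033, 0.0594 and -0.255 and those of controls 2 and 3 at 0.284 and -0.145. These values showed no steady pairing, but they are too few to settle whether the numbers pair the libraries. The forestomach groups shared a single number, and no block was fitted there.

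Of the named gene results 215 kept their side of the threshold with the GC covariate, 34 were lost and 4 gained, and with one slope sign 162 kept it and 91 were lost. All 37 camera calls of lists were lost with an estimated correlation, 6 with fry and 0 with the GC covariate, and of the list results without a single library 224 kept their call and 12 were lost, most of them without forestomach control 5. Simulated 2-fold changes were recovered for 33.5% of genes or fewer, so changes of that size are often missed.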

Other observations

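The tests of GC-linked bias, of a shared response, of Gata4 and of the cells outside the epithelium, and every value with a GC covariate or spline or from libraries of one slope sign, were chosen after the results were seen.

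Among enzymes of retinoic acid metabolism Aldh1a1 moved in opposite directions in the mutant groups, with and without the slope covariate. It fell by 1.38 in knockout libraries (SE 0.24, adjusted p = 0.00492) and rose by 2.54 in the libraries labelled knock-in (SE 0.27, adjusted p = 0.000518), and it was higher by 1.47 in control hindstomach than in control forestomach. Aldh1a2, which is also a mesothelial gene, rose by 1.73 in the former and stood at -2.15 in the latter, a call lost with the slope covariate (-1.55, adjusted p = 0.0563). The receptor gene Rarb rose by 1.21 in knockout libraries (SE 0.16, adjusted p = 0.00117), and Cyp26a1, which degrades retinoic acid, stood at -1.5 in the libraries labelled knock-in (SE 0.31, adjusted p = 0.0222). As a list the pathway did not pass camera in either mutant group or between control regions (adjusted p = 0.792, 0.166 and 0.0709, the last of them 0.0111 with the slope covariate and 0.21 there with an estimated correlation), with 2 of 13 genes risen and 3 fallen in knockout libraries (median -0.124). In that comparison the slope covariate gave 6 risen and 1 fallen (median 0.574, camera adjusted p = 0.0624). Lgr5 fell by 0.92 in knockout libraries (SE 0.19, adjusted p = 0.0105), against its rise of 3.38 in the libraries labelled knock-in.

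Sex was not given in the labels, and the X-inactivation transcript Xist and Y-linked genes split the libraries. Xist stood at 183 to 258 FPKM in hindstomach controls 2, 3 and 4 and at 296, 254 and 214 FPKM in the libraries labelled knockout 1, 4 and 5, against 0.617 and 0.312 in those labelled 2 and 3. In the forestomach it was 49.6 and 136 FPKM in controls 2 and 3, 0.341 in control 5 and 0.248 to 0.328 in the libraries labelled knock-in. The Y-linked Eif2s3y stood at 52.9 and 48.4 FPKM in knockout replicates 2 and 3, 78.4 in forestomach control 5 and 81.6, 72.3 and 50.2 in the libraries labelled knock-in 1, 2 and 4. Y-linked expression was thus present in 3 of 3 libraries labelled knock-in against 1 of 3 forestomach controls, and in 2 of 5 knockout libraries against 0 of 3 hindstomach controls. All 6 libraries with it were among the 7 with a GC slope below 0. Sex was therefore not separated from the knock-in comparison or from the slope used as a covariate.

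The knockout and knock-in fold changes correlated at 0.478 across genes although the labels name opposite changes of Gata4. With the GC slope as a covariate it was -0.382, and 0.18 after a GC spline was removed. Both corrections also remove a shared response that itself follows GC content, so a response shared by both mutants cannot be told apart from a bias. A GC-linked library bias is a candidate explanation, since among libraries of one slope sign the correlation was -0.419. That value rests on the libraries labelled knockout 4 and 5, with slopes above 0, and on forestomach control 5 alone for the knock-in. The knockout fold changes there still correlated with GC content at -0.302. A transcript length covariate also reversed the correlation (-0.377), so the bias is not tied to GC content alone. Chance was not excluded for the positive value, which 24 of 100 relabelings within each region reached (highest other 0.814), and 8 reached the negative value with the covariate. Both counts include the real labels. The size of any real relation stays open, because a simulated GC-linked bias alone gave 0.929 without the covariate and still 0.302 with it.

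Gata4 was not higher in the libraries labelled knock-in. A GC-linked loss of Gata4 reads, whose GC content is 57.4%, stays open, because against forestomach control 5, the control of the same slope sign, the log2 fold change was 0.036 with an upper 95% limit of 1.13, which does not exclude a 2-fold higher level. The covariate fit over all libraries gave 0.30 (SE 0.28) with an upper limit of 0.944, just under 2-fold, but Gata4 lay near the floor in these libraries, where such a limit excludes little. With the covariate 75 genes fell in knockout libraries and rose here, where independent lists would share 15. Genes that move together, as with sex or the share of cells outside the epithelium, could also give such an excess. The excess therefore does not settle whether these are control libraries. An added copy whose transcript is not counted under the Gata4 gene could also leave the level low, and that was not tested.

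The mesenchyme list was placed up in knockout libraries (15 of 26 genes risen) and down in the libraries labelled knock-in (4 fallen, and 0 of them also with the covariate). With the GC covariate the medians of all 6 other lists of cells outside the epithelium lay more than 0.5 from 0 in knockout libraries. Camera passed the smooth muscle, leukocyte, enteric and mesothelium lists there, but not endothelium and red blood cells (adjusted p = 0.312 and 0.16). With an estimated correlation the former 4 did not pass either (adjusted p = 0.452, 0.57, 0.419 and 0.441). As deposited, smooth muscle and leukocytes did not pass camera (adjusted p = 0.0794 and 0.104). These values go against a change in mesenchymal cells alone but do not settle it. A different share of all cells outside the epithelium in the isolates may account for the mesenchyme pattern with the covariate. There 14 of 14 medians over 7 lists were above 0 in knockout libraries or below 0 in those labelled knock-in, with mesenchyme at 1.5 and -1.37 and red blood cells at 0.88 and -1.24. With FPKM as deposited 13 of 14 were, and the knockout medians of red blood cells (-0.44) and leukocytes (0.33) lay over 1 below that of mesenchyme (1.43), so this cannot be told apart from a change in some of these cells. The test was recast to the covariate fit after an earlier form had been run, in which all 8 mesenchyme genes of highest FPKM, such as Sparc, Col3a1, Vim and Dcn, went in the stated directions. Of the 26 mesenchyme genes 19 had an FPKM of at least 1 in every control library and 0 stood on another list.

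Other splits of the libraries were counted for each number of called genes. For the knockout 2 of 56 splits called at least the real 1680 genes. The other split called 4375 genes and parted knockout replicates 1 to 3, with slopes below 0, from the rest, which points to that structure of the samples. The count with FPKM as deposited thus does not exclude a chance alignment of the labels with that structure. With the GC covariate 1 of 56 splits reached the real 1555, with 2 as the highest other. In the knock-in comparison the 10 splits are too few for a share under 0.05. The real 742 was exceeded by a split that called 6827, so 2 of 10 reached it. That split set forestomach controls 2 and 3 with the library labelled knock-in 4, which again follows the slope. The titles of these libraries also open with neighbouring numbers, apart from those of the other forestomach libraries. The labels do not say what these numbers mean, so the slope cannot be told apart from such an order of the samples. With the covariate the real 696 stood against a highest other of 54 (1 of 10). Between control regions 10 splits are again too few, with a real 2583 against a highest other of 1, and 5325 against 1 with the covariate (1 of 10 each). Genes called in opposite directions in the mutant groups numbered 111 against a highest other of 23 over 100 relabelings (1 of 100), and 165 against 5 with the covariate (1 of 100), each share being the real labels alone. Other relabelings gave a median of 0 such genes because they called few genes at all, so labels that call many genes would rank first in any case. The rank therefore does not exclude a chance alignment of the labels with the slope, sex or title numbers. Chance was not tested for the direction of these genes.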
